A study of Drosophila melanogaster with 3 samples.

How the data were processed

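ChIP-seq peak lists were analysed for 3 biological replicates of 1 group: whole white prepupae, both sexes pooled, of a fly line carrying Smox fused to GFP, immunoprecipitated with an anti-GFP antibody. Per the labels, chromatin was fragmented by sonication and fragments of 200 to 800 bp were taken. Replicate numbers come from the labels, which call them biological replicates.

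Per the file listings deposited with the samples, peaks and background regions were called by the authors on each replicate alone and on the pooled replicates, each time with 1 control alignment, and the thresholded list was derived from the replicate and pooled lists by the irreproducible discovery rate (IDR). The aligner, the peak caller, the IDR cutoff and the nature of the control are not given in the sources used here. Each deposited line gives an interval, a score from the authors' peak caller whose scale is not stated, a −log10 q-value as deposited, and the offset of the summit in bp. The column for p-values is not filled in the deposited lists. Scores were used only to rank regions within a list. Every unthresholded list had 30000 lines, so ranks of different replicates refer to lists of equal length. The thresholded list held exactly the 6622 highest-scoring regions of the pooled list on dm6, and the 6607 highest on dm3. In the dm6 list 54 thresholded lines shared their interval with an earlier line and carried another summit, and 2 summits 1 bp past their interval were held at its last base. Replicates were compared for duplicated deposits: replicates 1 and 2 shared 292 identical intervals, none with an identical score, and the other pairs shared none. Read counts were not given, so depth is unknown, and intervals on shares of peaks or genes cover counting error only.

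Each replicate list was cut to as many regions as the thresholded list (its strongest regions) to give values per replicate with mean and SD. Overlap needed 1 bp. The chance level came from 100 shuffles of the thresholded peaks within chromosomes. Summits were assigned, in this order, to promoters (within 500 bp of any annotated TSS), 5′ UTRs, coding exons, 3′ UTRs, other exons, introns and intergenic sequence, with the Ensembl release 115 annotation of BDGP6.54, and compared with 1000 sets of random positions on the same chromosomes. The dm6 assembly has the sequence of Release 6, and no coordinate was converted between builds. Comparisons with genes and sequence used chromosomes 2L, 2R, 3L, 3R, 4 and X. The mitochondrial genome and dm3's extra contigs were left out of them.

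A protein-coding gene was called bound when a thresholded summit lay within 1 kb of any of its TSSs. The 22 gene lists, the 26 sequence elements, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, and adjusted p-values are Benjamini-Hochberg values over the 22 lists with a threshold of 0.05. All list members were matched to the annotation, 10 of them through older symbols. The lists hold 780 distinct genes, 13 of them in more than one list. Motif windows reached 75 bp either side of a summit, and control windows of the same size were centred 500 bp away on a side drawn at random. Motifs and hexamers were counted on both strands and compared with exact McNemar tests, two-sided, adjusted within each family. Genes named are the nearest protein-coding genes of the 20 strongest thresholded peaks covered in all 3 replicates, up to 4 bound members with the strongest peaks and up to 2 unbound members in alphabetical order per list, and Smox, Mad, Med, babo, put, EcR and Dad in any case. Ranks given for a gene are those of its strongest summit within 1 kb of a TSS, except for the 20 strongest peaks.

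Alternatives tried were the strongest 1000 peaks, ranking by −log10 q-value, only peaks covered in all 3 replicates, leaving out each replicate, the top of the pooled list in place of the thresholded list, other promoter, gene and motif windows, other control windows, gene-length-matched random lists and peak density per sequence length. Random lists matched on the number of TSSs (up to a ceiling of 8) and on 3 classes of gene length were added after the data had been seen. So were lists matched on length for summits in the gene body, and the closing tests marked there. No condition was contrasted, so no paired design and no regrouping of samples applies.

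The functions were tested on simulated data. With 100 simulated sets of bound genes among 13968, 97.5% of lists planted at 60% bound were called, and 2% of sets with nothing planted gave a call. These sets were drawn evenly over all genes, so the 2% does not cover effects of gene length or number of TSSs. A hexamer planted in 10% of 6599 windows ranked first with a gain of 9.62 percentage points, while 4 of 2080 hexamers and 0 of 26 elements were called with nothing planted. Both sides of this simulated comparison were windows away from summits. The counts therefore do not cover calls that arise from a GC difference between summits and flanks. With 80.0% of 6600 peaks kept and shifted by at most 50 bp, 81.8% were found, since neighbours can overlap. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.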

Results

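Smox is the Drosophila SMAD protein that carries Activin-type TGF-beta signals from the receptor babo to the nucleus. Chromatin was immunoprecipitated with an anti-GFP antibody from whole white prepupae, the animals at the moment of puparium formation, of a line expressing Smox with GFP at its C terminus. Males and females were pooled. The data comprise 1 group of 3 biological replicates, so no condition was contrasted with another, and the comparisons are between replicates, between peaks and the rest of the genome, and between gene groups. Each replicate was represented by a list of 30000 called regions, ranked by the score the authors' peak caller gave each region. A list of 30000 regions from the pooled replicates and a reproducibility-thresholded list of 6622 peaks covered the series. The thresholded peaks had a median width of 444 bp and spanned 2.51 Mb of interval length. The lists hold no read counts, so the sequencing depth of each replicate is unknown. Coordinates are on the dm6 assembly unless stated.

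The same sites ranked highest in all replicates. The strongest peak of the pooled data, at 3L from 19590387 to 19590853 and at -99 bp relative to the transcription start site (TSS) of CG14100, was ranked 1 in each of the 3 replicate lists. Peaks at Ugalt, a UDP-galactose transporter, and at the mitochondrial RNA-processing enzyme gene PNPase were among the 5 strongest regions of every replicate. When each replicate list was cut to its 6622 strongest regions, it covered 86.7% ± 2.13 (SD, n = 3) of the thresholded peaks. All 3 replicates covered 4755 peaks (71.8%), exactly 2 covered 1175, exactly 1 covered 616, and none covered 76. Peaks shuffled within chromosomes were covered by all 3 replicates in 2.54% of cases on average and 3.04% at most (one-sided permutation p = 0.0099, the smallest that 100 shuffles can give). Of the strongest 1656 peaks 98.7% were covered in all 3 replicates. The weakest 1655, of which 17.1% were, lie at the limit at which the replicate lists were cut. Against the whole replicate lists, the share of thresholded or optimal peaks in all replicate lists was 97.9%. Across the thresholded peaks, the scores of replicate pairs had Spearman rho of 0.859, 0.865 and 0.855. The mean was 0.86, and for the rank agreement of replicates by −log10 q-value it was 0.476. Peaks are not independent replicates, and the thresholded list was itself made from these replicates, so these values describe agreement and are not an independent test.

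Smox summits lay at promoters and in introns and almost never in coding exons. Of 6600 summits on the nuclear chromosomes, 2198 (33.3%) were within 500 bp of a TSS, 2.46 times the 13.5% of random positions on the same chromosomes (one-sided permutation p = 0.001, the smallest that 1000 sets can give). In the 3 replicate lists the promoter share was 36.6% ± 0.744 (SD, n = 3). Introns held 44.1% of summits against 39.6% of random positions, and intergenic sequence held 20% against 27.1%. Coding exons away from promoters held 9 summits, or 0.136% (95% Wilson interval 0.0718 to 0.259), against 13.7% of random positions. The replicate lists gave 0.146% ± 0.0315 (SD, n = 3). The 3′ UTRs held 0.788% of summits against 4.46% of random positions. Promoter summits were more frequent among strong peaks, with 42.2% of the strongest 1650 summits against 28.2% of the weakest 1650 (two-sided Fisher's exact test, p = 3.18e-17). The same difference was present in each replicate list, with odds ratios of 1.65, 1.67 and 1.87.

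**Figure D1:**
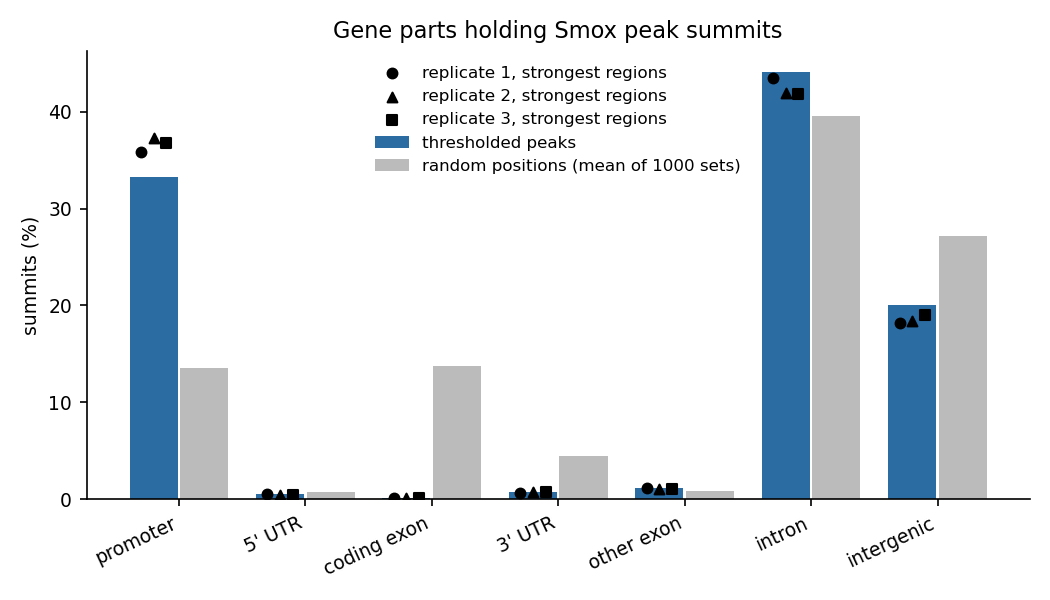
Percent of summits in each part of the gene annotation, for the 6600 thresholded nuclear peaks (blue bars), random positions on the same chromosomes (grey bars) and the strongest regions of each replicate list (points). Promoters within 500 bp of a TSS hold 33.3% of summits against 13.5% of random positions, and coding exons hold 0.136% against 13.7%.

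The 20 strongest replicated peaks, 1 per nearest gene, lay both at promoters and far from them. The peaks at Ugalt, PNPase, CG18549, CenG1A, Tcs5, the chromatin protein gene Chro, CG1888, larp (a regulator of mRNA translation) and CG9147 lay between 9 and 336 bp from the nearest protein-coding TSS. Others were distal. The third-ranked peak, at 2L from 480548 to 481351, lay inside ush, which encodes a GATA cofactor, and at -1368 bp relative to the TSS of cbt. A peak inside osa, a subunit gene of the Brahma chromatin remodelling complex, was 13930 bp downstream of the TSS. A peak inside Eip75B at 3L from 18011639 to 18012140 was ranked 13 in the pooled data and 21, 12 and 15 in replicates 1, 2 and 3. The eEF1gamma peak lay at -5737 bp. The remaining genes nearest to these peaks were CG11050, Lk6, CG13323, CG32772, CG31668 and CG16753.

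In total 2639 of 13968 protein-coding genes (18.9%) had a thresholded summit within 1 kb of a TSS and are called bound below. The strongest regions of the replicate lists gave 2945 ± 106 bound genes (SD, n = 3), of which 2138 were bound in all 3, and 2041 of those were also bound in the thresholded list.

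The pathway of Smox made up 1 list: TGF-beta and BMP pathway genes, of which 10 of 28 (35.7%) were bound. Each replicate list gave the same 35.7%. The share in other genes was 18.9%, and the pathway did not pass the correction over 22 lists (odds ratio 2.39, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0659). Random lists matched on gene length had 28.9% bound by the 1 kb rule. Counted over the whole gene body the pathway passed (odds ratio 4.62, Fisher's exact test, adjusted p = 0.000218). Random lists matched on gene length had 42.2% bound by that count, and against them the pathway did not pass (adjusted permutation p = 0.161). The bound members with the strongest peaks were the coactivator gene nej, the BMP repressor gene brk, its regulator shn, and Mad, the BMP-branch SMAD. The nej and brk peaks had pooled ranks of 839 and 845, that of shn 1370, and that of Mad 2122. The receptor gene babo (pooled rank 2367, 863 bp from the TSS) and Dad, which encodes the inhibitory SMAD (rank 2503, 428 bp), were bound in all 3 replicates. The genes of the co-SMAD Med, the ligand Actbeta and the receptor put were not bound, although put had a peak among the strongest regions of replicate 2. Smox itself had no thresholded summit in the gene or within 1 kb of it.

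Ecdysone-response genes were bound in 19 of 29 cases (65.5%), against 18.8% of other genes (odds ratio 8.21, Fisher's exact test, adjusted p = 3.49e-07). The replicate lists gave 64.4% ± 1.99 (SD, n = 3). Ecdysone is the steroid hormone whose pulse triggers puparium formation. The strongest peaks of the list were at Sox14, a transcription factor gene of neuron pruning (pooled rank 41, with 38, 43 and 48 in the replicates), the transporter gene E23 (rank 159) and the nuclear receptor genes Hr3 (rank 263) and Eip75B (rank 358 for its peak near a TSS). EcR, which encodes the ecdysone receptor, had a peak 503 bp from a TSS with a pooled rank of 2927. Cth and Cyp18a1, an ecdysone-degrading enzyme gene, were not bound. Eip75B, at 3L from 17950953 to 18064696, contained or adjoined 17 thresholded summits, and EcR 9. The genes of ecdysteroid synthesis were bound in 1 of 16 cases, shd (6.25%, Fisher's exact test, adjusted p = 0.492), and the replicate lists gave 10.4% ± 7.22 (SD, n = 3). Cyp6t3 and Npc1a were not bound.

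**Figure D2:**
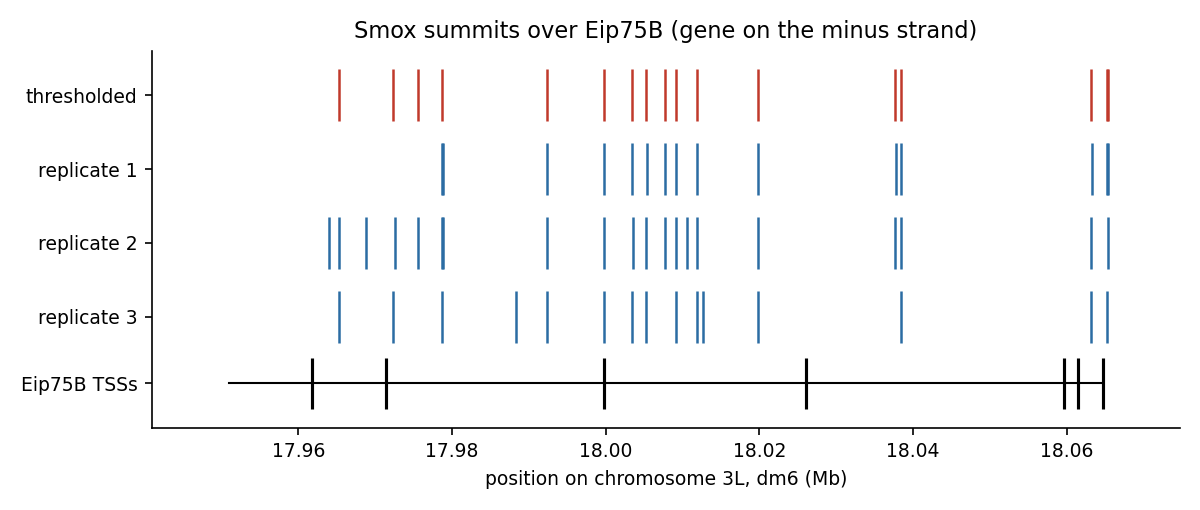
Summits of thresholded peaks (red) and of the strongest regions of replicates 1 to 3 (blue) along Eip75B and 10 kb either side on chromosome 3L of dm6, with the 7 annotated TSSs of the gene (black) below. The gene contained or adjoined 17 thresholded summits.

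The list of mushroom body remodelling and temporal identity genes, which includes babo, was bound in 13 of 20 cases (65.0%, odds ratio 8.01, Fisher's exact test, adjusted p = 2.84e-05). It shares 7 members with other lists, Sox14 and EcR among them. Its strongest peaks beside Sox14 were at usp, encoding the partner of the ecdysone receptor, at Mical and at Syp, while Cul1 and Dscam1 were not bound. Hippo pathway genes were also bound in 13 of 20 cases (65.0%, Fisher's exact test, adjusted p = 2.84e-05, replicates 63.3% ± 2.89, SD, n = 3). The atypical cadherin gene ds, the caspase inhibitor gene Diap1, ex and app had peaks with pooled ranks of 128, 412, 488 and 796. Dlish and Myc had no summit near a TSS, although Myc had 4 in the gene or within 1 kb of it. Notch pathway genes were bound in 10 of 22 cases (45.5%, odds ratio 3.59, Fisher's exact test, adjusted p = 0.0125, replicates 50% ± 7.87, SD, n = 3), with fng, E(spl)m3-HLH, E(spl)m7-HLH and aph-1 the strongest. Delta, which had a summit near a TSS among the strongest regions of replicate 2, and E(spl)m5-HLH were not bound. Tracheal and epithelial genes were bound in 7 of 16 cases (43.8%, Fisher's exact test, adjusted p = 0.0483), led by crb, grh, trh and shg. The crb summit, at pooled rank 76, lay 998 bp from the TSS, just inside the 1 kb limit. The matching replicate regions (ranks 80, 68 and 75) had summits 1005 to 1012 bp away. In none of the 3 replicate lists did this list pass on its own, with adjusted exact p between 0.15 and 0.479. The genes bnl and btl were not bound. Long genes have more TSSs and more sequence. Against 10000 random lists matched on gene length, the ecdysone, mushroom body, Hippo and ribosomal protein lists still passed. The Notch list had an adjusted permutation p = 0.0842, and the tracheal list 0.547. The length-matched lists had 32.1% bound for the ecdysone list, 34.9% for the mushroom body list and 29.5% for the Hippo list. For these 3 lists the contrast is therefore smaller than with all other genes. Against random lists matched on the number of TSSs and on 3 classes of gene length, the ecdysone, Hippo, Notch and ribosomal protein lists passed. There the mushroom body list had an adjusted permutation p = 0.093 and the tracheal list 0.468. These matched lists had 37.65% bound for the ecdysone list, 40.3% for the mushroom body list and 28.4% for the Hippo list.

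Short genes made up another list: ribosomal proteins, whose genes were bound in 51 of 85 cases (60%, 95% exact interval 48.8 to 70.5), against 18.6% of other genes (odds ratio 6.55, Fisher's exact test, adjusted p = 1.2e-15). Length-matched random lists had 13% of members bound. The replicate lists gave 51.8%, 71.8% and 68.2%. The strongest peaks were near RpS19b, RpL32, RpS28b and RpL34b, with pooled ranks between 240 and 587, and RpL10Aa and RpL11 were not bound. Among the strongest 1000 peaks alone the list was no longer called (odds ratio 1.67, Fisher's exact test, adjusted p = 0.572), nor were the ecdysone, mushroom body, Hippo and tracheal lists.

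In 3 lists fewer genes were bound than elsewhere. Chemosensory receptor genes were bound in 2 of 179 cases (1.12%, odds ratio 0.0478, Fisher's exact test, adjusted p = 6.54e-13), Ir94h and Ir60a (994 bp from the TSS), with Gr10a and Gr10b among the unbound. Cuticle protein genes were bound in 5 of 121 cases (4.13%, Fisher's exact test, adjusted p = 1.78e-05), led by Cpr72Eb, Cpr62Ba, Cpr49Ah and Cpr47Ec. Ccp84Aa and Ccp84Ab were not bound. None of the 22 salivary glue and early-late puff genes, such as Eig71Ea and Eig71Eb, was bound in the thresholded list or in any replicate list (adjusted p = 0.0383, exact 95% upper limit 15.4%). Length-matched random lists had 9.11% bound, and against them that list did not pass (adjusted permutation p = 0.446). The tests and intervals treat genes as independent, but neighbouring genes can share a region. Eig71Ea and Eig71Eb, for example, had the same region, ranked 25678, near their TSSs in the full list of replicate 1.

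**Figure D3:**
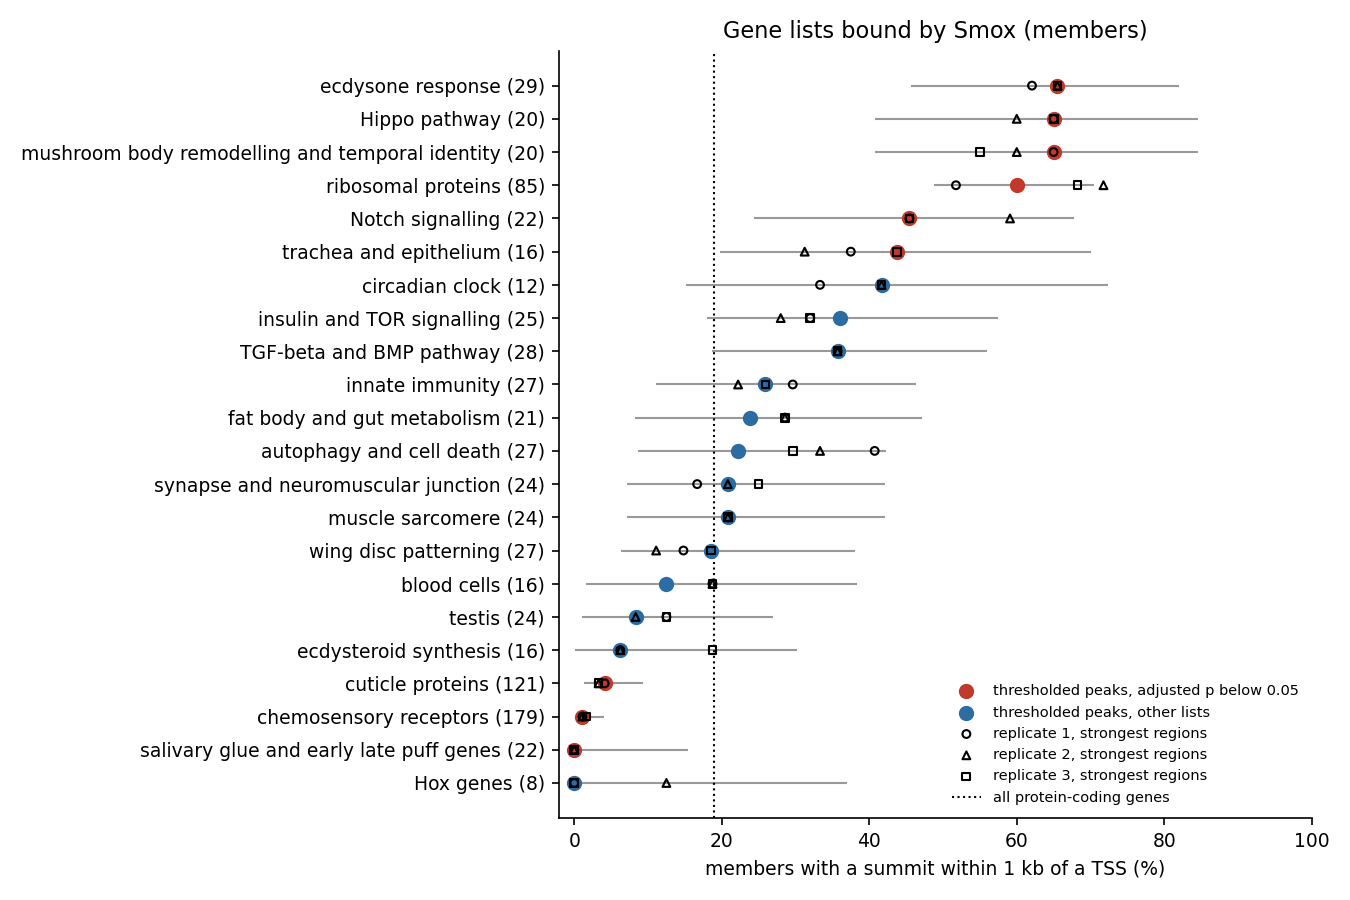
Percent of the members of each gene list with a thresholded summit within 1 kb of a TSS (filled circles, with exact 95% binomial intervals), and the same from the strongest regions of each replicate (open symbols). Red circles mark the 9 lists with an adjusted p below 0.05, and the dotted line is the 18.9% of all protein-coding genes.

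The other lists did not pass in either direction by the 1 kb rule. Insulin and TOR genes were bound in 9 of 25 cases (36%, Fisher's exact test, adjusted p = 0.0777), with the TOR-responsive factor REPTOR at pooled rank 78, followed by foxo, InR and Akt. Ilp1 and Ilp2 were not bound. Clock genes were bound in 5 of 12 cases (41.7%, Fisher's exact test, adjusted p = 0.108), with vri, cry, Pdp1 and dco bound and Clk and Pdf unbound. Innate immunity genes were bound in 7 of 27 cases (25.9%), with imd, cact, dl and PGRP-LB the strongest and AttA and AttB among the unbound. Metabolic genes of fat body and gut were bound in 5 of 21 cases (23.8%), led by SREBP, Hnf4, bmm and FASN1, with AkhR unbound. ACC was also unbound, although all 3 replicate lists had a strong region near its TSS. Autophagy and cell death genes were bound in 6 of 27 cases (22.2%), including hid, Diap1, Atg17 and Atg8a but not Atg1 or Atg101. The replicate lists gave 34.6% ± 5.66 (SD, n = 3), and in replicate 1 the list passed (adjusted exact p = 0.039). Synaptic genes and muscle genes were each bound in 5 of 24 cases (20.8%). The bound synaptic genes included elav, Syx1A, Nrx-1 and dlg1 but not ChAT or Gad1, and the bound muscle genes included Msp300, Zasp52, Tm1 and Mef2 but not Act57B or Act79B. Wing disc patterning genes were bound in 5 of 27 cases (18.5%), among them rho, Dll, dac and sd but not Doc1 or al. Counted over the whole gene body 16 were bound, but not more than in length-matched lists (adjusted permutation p = 0.679). Blood cell genes were bound in 2 of 16 cases (12.5%, PPO3 and ush), with Col4a1 and He unbound. Testis genes were bound in 2 of 24 cases (8.33%, Dhod and can), with Mst84Da and Mst84Db unbound. None of the 8 Hox genes, Abd-B and Antp among them, had a summit within 1 kb of a TSS, although Antp had 10 in the gene or within 1 kb of it.

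Summits were AT-rich. The 151 bp centred on a summit had a mean GC content of 33.3%, against 43.7% in windows of the same size centred 500 bp away, and the replicate lists gave 32.9%, 34.4% and 34.0%. Among 26 fixed sequence elements, 5 were more frequent at summits than in the flanking windows and 13 less frequent (exact McNemar test with Benjamini-Hochberg adjustment). The SMAD box GTCT was present in 41.2% of summit windows against 48.0% of flanking windows (exact test, adjusted p = 2.61e-14), and the GC-rich SMAD element GGCGCC in 1.53% against 2.33%. The control string GGAGA differed in the same direction (11.9% against 21.8%). The elements more frequent at summits were the TATA box (12.5% against 5.03%), the homeodomain core TAATTA (14.8% against 8.55%), the DRE TATCGATA (1.14% against 0.258%), the M1BP motif GGTCACAC (0.955% against 0.348%) and the BEAF-32 core CGATA (17.5% against 15.5%).

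Weaker regions of the pooled list with the same GC content gave a different comparison. Against these, the SMAD box was present in 41.2% of summit windows and 41.7% of matched windows, a difference of -0.47 percentage points (95% interval -2.15 to 1.21, Fisher's exact test, adjusted p = 0.875). The matched regions were themselves listed regions. An element shared by stronger and weaker regions would therefore give no difference here, and this comparison cannot tell whether it is enriched over the genome. Against summit sequence shuffled with its dinucleotides kept, which fixes GC content too, the SMAD box stayed less frequent (41.2% against 49.3%, exact test, adjusted p = 1.39e-20). GGCGCC (1.53% against 0.879%, exact test, adjusted p = 0.00232) and the Mad site GCCGNCGC (0.606% against 0.303%, exact test, adjusted p = 0.029) were more frequent than in shuffled sequence. So was the control string GGAGA (11.9% against 10.2%, exact test, adjusted p = 0.0034). The remaining SMAD elements did not pass there. Against the GC-matched regions, the DRE, M1BP motif and BEAF-32 core remained more frequent at the thresholded summits. Fisher's exact test gave adjusted p = 0.0359, 0.0127 and 0.017. The BEAF-32 call against the flanks ended without replicate 3 (exact McNemar test, adjusted p = 0.283) and with flanks 1000 bp away (adjusted p = 0.191). The matching did not cover promoter share. That share was 33.3% for the thresholded summits and at most 22.3% in rank bands of the weaker pooled regions. Whether the excess of the DRE, M1BP and BEAF-32 elements over the GC-matched regions follows from promoter share was not tested. Against the GC-matched regions TAATTA was less frequent (14.8% against 16.6%, Fisher's exact test, adjusted p = 0.0359) and the TATA box did not differ past the threshold (adjusted p = 0.478). At summits over 500 bp from any TSS, the DRE, M1BP and BEAF-32 elements no longer passed against flanking windows (exact McNemar test, adjusted p = 0.824, 0.126 and 0.764). The ratio to the flanks fell from 4.41 to 1.22 for the DRE and from 1.13 to 1.02 for the BEAF-32 core, but only from 2.74 to 2.11 for the M1BP motif. Among all 2080 hexamers merged with their reverse complements, 596 were more and 1124 less frequent at summits than in the flanks. These counts were 52 and 42 against the GC-matched regions. The 20 with the largest gain over the flanks consisted of A and T alone, led by AAATAT (46.5% against 20.5%).

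**Figure D4:**
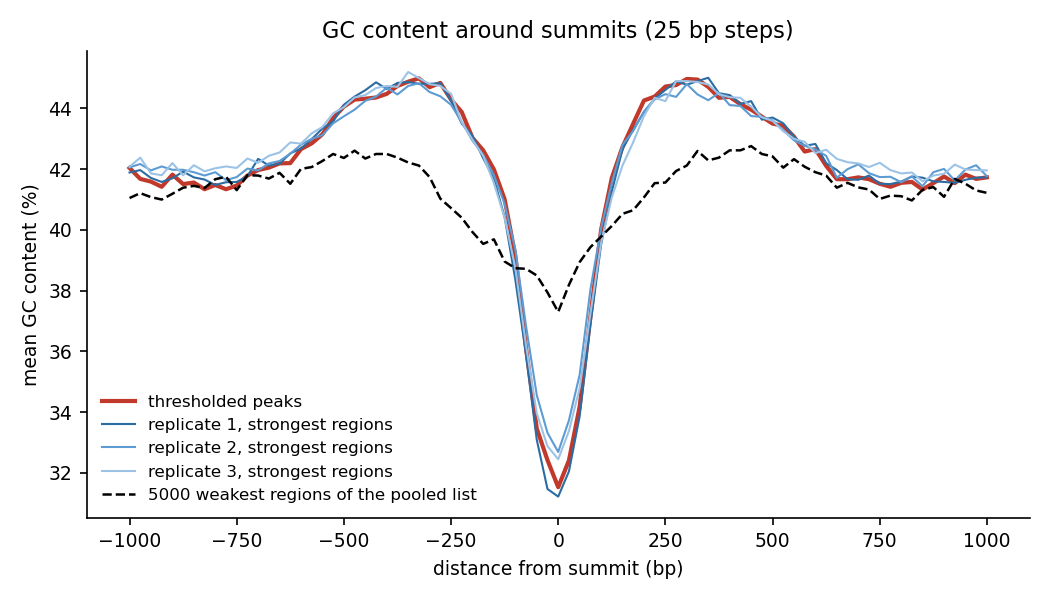
Mean GC content in 25 bp steps around summits, for the thresholded peaks (red), the strongest regions of each replicate list (blue lines) and the 5000 weakest regions of the pooled list (dashed). At the summit the thresholded peaks reach 31.5% and the weakest regions 37.3%.

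The X chromosome carried more peaks for its genes than the autosomes. It had 62.2 peaks per 100 protein-coding genes (1367 peaks), against 45.1 on 2L, 37.7 on 2R, 54.0 on 3L and 42.7 on 3R. The ratio of X to the large autosomes was 1.39 (two-sided exact binomial test on peaks, expectation from gene numbers, p = 4.67e-26) and 1.34 ± 0.0584 (SD, n = 3) in the replicate lists. Per sequence length the ratio was 1.21 (exact binomial p = 3.82e-10). Chromosome 4 had 19 peaks, or 23.8 per 100 genes, with 26.7 ± 7.11 (SD, n = 3) in the replicate lists. The binomial test treats peaks as independent, which neighbouring peaks are not. It also pools the large autosomes, which differed among themselves, from 37.7 peaks per 100 genes on 2R to 54.0 on 3L. Per Mb, X had 58.1 peaks, 3L 52.6 and 2R 42.55. The p-values therefore do not show that X lies beyond the spread among chromosome arms.

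**Figure D5:**
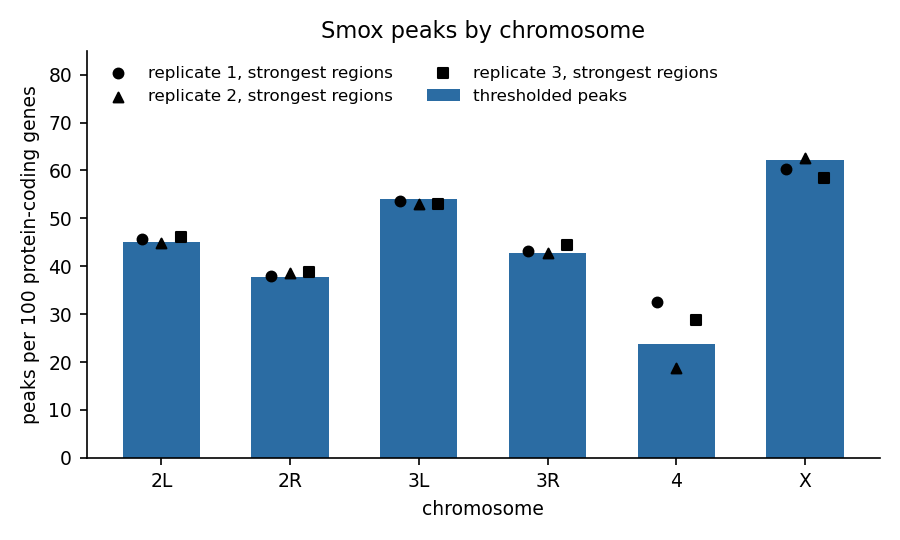
Thresholded Smox peaks per 100 protein-coding genes on each chromosome (bars) and the same for the strongest regions of each replicate list (points). The X chromosome has 62.2 and chromosome 4 has 23.8.

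The authors deposited the lists on 2 builds of the genome. The thresholded list had 6622 peaks on dm6 and 6607 on dm3. On both builds 6600 of these lay on the nuclear chromosomes X, 2, 3 and 4. The share of thresholded or optimal peaks in all replicate lists was 71.8% on dm6 and 71.7% on dm3.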

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

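No test was run on these counts, and none was chosen after they were seen. Peaks outside the nuclear chromosomes entered the comparisons between replicates but none of those with genes and sequence. On dm6 the thresholded list placed 22 peaks on the mitochondrial genome, which are all the mitochondrial regions of the pooled list. The replicate lists of 30000 regions had 23, 26 and 17 regions there, and the thresholded list on dm3 had 3. On dm3 the thresholded list also placed 4 peaks on heterochromatic contigs, 1 on 2RHet, 2 on 3LHet and 1 on XHet. The cause of neither was tested.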

How the results depend on the processing

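The random lists matched on the number of TSSs, and those matched on length for summits in the gene body, were added after the results were seen, and all other alternatives were planned. Taking the top of the pooled list moved nothing, since that is the thresholded list. The promoter share, its difference by strength and the X ratio kept direction and threshold in all their alternatives. The promoter share ranged from 23% (250 bp window) to 48.2% (strongest 1000 peaks), and the X ratio from 1.21 (per length) to 1.41. The share of thresholded, or optimal peaks in all replicate lists was 63.6% with 50% of the peak required, 97.9% against whole replicate lists and 80.7% among the strongest 1000 of each list. It was 76.1 to 79.2% without one replicate, when only 2 lists must cover a peak. The mean rho was 0.476 by −log10 q-value, 0.89 over peaks in all 3 lists, and 0.855 to 0.865 without one replicate. Bound genes numbered 715 for the strongest 1000 peaks and 5142 with a 5 kb window.

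The lists bound more often numbered 6 and ranged from 4 to 8, except for 1, the Notch list, among the strongest 1000 peaks, where fewer genes are bound. There the mushroom body list had an odds ratio of 0.976. With summits anywhere in the gene, the direction turned with a call for 1 list: wing disc patterning genes, which had not passed at 0.976, had an odds ratio of 4.35 (Fisher's exact test, adjusted p = 0.000416). Hox genes turned without passing in either setting. Against length-matched lists with the same count, wing disc, TGF-beta and Hippo genes did not pass (adjusted permutation p = 0.679, 0.161 and 0.0823). The strongest 1000 peaks also ended the call of the list: ecdysone response (odds ratio 2.98) and of the list: Hippo pathway (4.65). The tracheal and salivary lists lost their call in 10 of 13 alternatives each, among them leaving out any 1 replicate. The TSS-matched lists ended the calls of the mushroom body (adjusted permutation p = 0.093), tracheal and salivary lists. Of 87 named bound genes 24 lost their summit with a 500 bp window, and 1 to 5 did so without one replicate.

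The motif results depended on the control windows. Elements more frequent at summits numbered 2 for the strongest 1000 peaks, 3 against GC-matched regions, 8 against shuffled summit sequence and 2 away from TSSs. Those less frequent numbered 1 against GC-matched regions and 3 against shuffled sequence. Enriched hexamers numbered 384 for the strongest 1000 peaks, 52 against GC-matched regions and 330 against shuffled sequence, and depleted ones 42 and 526 against the latter pair. Among elements that had passed against the flanks, these turned direction against GC-matched regions: GGCGCC (ratio 1.23), GAGAG (1.11), CAGCTG (1.17), AP-1 (1.09), TAATTA (0.893), the TATA box (0.934) and the control CCGCGG (1.21). Of these only TAATTA passed in the new direction. Against shuffled sequence GGCGCC (1.74), the Mad site (2.0), GAGAG (1.5), CAGCTG (2.33), TEAD (1.06), TAATTA (0.877) and the strings TCTG (1.03) and GGAGA (1.17) turned direction. All of the latter but TEAD passed in the new direction. CGATA also lost its call over peaks in all 3 lists (1.06), without replicate 3 (1.05), with flanks 1000 bp away (1.06) and against shuffled sequence (1.08). Among the strongest 1000 peaks CGATA (0.947) and the M1BP motif (0.333) turned direction, and the DRE lost its call with a ratio of 3 (adjusted exact p = 0.418). GC content is fixed by construction in both controls. The cause of the other changes was not tested. Depth could not be examined.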

Other observations

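The tests on coding exons at matched GC and on the empty stretch around Smox, and the choice of the gene families below, were made after the results had been seen. Several genes held many summits in the gene or within 1 kb of it. The genes with the most were kirre, with 31 over 394 kb, sbb, with 24 over 79.1 kb, and Tet, with 22 over 92.9 kb. At the mean density of the genome 19.5, 4.0 and 4.68 would lie there. In the replicate lists these genes had 27.3 ± 3.06, 27.0 ± 2.0 and 22.3 ± 2.52 summits (SD, n = 3). The genes shn (20, where 2.97 would lie at the mean density), ush (18, 3.27), Mnt (17, 1.57) and Eip75B (17, 5.71) were also among the 25 with the most, and no test of their functions was made.

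Among 13 further families taken from gene symbols, mitochondrial ribosomal protein genes were bound in 24 of 73 cases (32.9%, odds ratio 2.11, Fisher's exact test, adjusted p = 0.022), with 35.2% ± 2.09 (SD, n = 3) in the replicate lists. Nuclear receptor genes were bound in 9 of 21 cases (42.9%, Fisher's exact test, adjusted p = 0.0299), a family that overlaps the ecdysone list. Proteasome subunit genes were bound in 2 of 48 cases (4.17%, exact test, adjusted p = 0.022; replicate lists 11.1% ± 4.81, SD, n = 3), odorant-binding protein genes in 2 of 51 (3.92%, adjusted p = 0.022) and cytochrome P450 genes in 7 of 85 (8.24%, adjusted p = 0.0299). Translation factor genes (22.6%), respiratory complex I genes (17.5%) and vacuolar ATPase genes (12.1%) did not pass. The families were not compared with random lists matched on gene length or number of TSSs, which ended the calls of the tracheal and salivary lists. Whether the calls of these families reflect gene length or number of TSSs is therefore open.

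The AT-rich summits outside coding exons may be technical or biological, and no biological explanation was tested. The gene parts in which peaks lie do not account for the base composition, since random positions on the same chromosomes and gene parts had 7.84 percentage points more GC than the summits. Base composition does not account for all of the shortage in coding exons, since 3.53% of random positions matched on chromosome and GC lay in coding exons, against 0.136% of summits (exact 95% upper limit 0.259%), a comparison whose bound replaced an earlier one, under 1% or over 5%, that the value had left undecided. An effect of calling, or of the control, shared by all listed regions stays open, and the reads and the control were not analysed here. The 5000 weakest regions of the pooled list had 38.3% of the GC drop of the thresholded peaks, between the bounds of 25% and 50% set beforehand, and the replicate lists had 49.3%, 31.7% and 17.4%.

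Summits within 1 kb of the TSSs of ribosomal protein genes could come from crowded neighbourhoods or from signal at any strongly transcribed gene. Ribosomal protein genes were bound 2.54 times as often as genes with as many protein-coding TSSs within 2 kb (51 against a mean of 20.1, one-sided permutation p = 0.0001, the smallest that 10000 lists can give). The number of TSSs at and around these genes thus does not account for their share. That number included the gene's own TSSs and all others between its first and last. Crowding by neighbouring genes was therefore not tested on its own and stays open. The genes of tRNAs, transcribed by another polymerase, had a summit within 1 kb in 32 of 290 cases (11.0%, exact 95% interval 7.67 to 15.2), below the 18.9% of protein-coding genes. The tRNA genes thus lacked the high share of the ribosomal protein genes (60%). Yet 11.0% is not low for short genes, since random protein-coding genes matched on length to the ribosomal protein genes had 13% bound. Transcription of the tRNA genes was not measured, so this comparison cannot exclude signal at strongly transcribed genes. An effect limited to RNA polymerase II promoters stays open, and so does a biological role of Smox there, which no group of the design tests.

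The labels describe a transgenic line but not the insert or its copy number, and extra copies of Smox sequence, if present, could raise the number of called regions around the gene. The pooled list had 0 regions within 20 kb of the middle of Smox, where other genes had a median of 7, so no added regions were seen there. The nearest pooled summits, at X positions 8100247 and 8178403, were 78156 bp apart with 22 genes wholly between them, and in replicates 2 and 3 the summits either side of Smox were 78094 and 77271 bp apart with the same 22 genes between, whereas replicate 1 had a summit at 8143737 and a distance of 43490 bp. Such an empty stretch may be ordinary, since 16.7% of 1488 partly overlapping windows of 20 kb either side of other genes with at least 14 genes in them had no listed region (5.82% of all windows). Windows of neighbouring genes can count the same empty stretch many times, so this share does not give the number of such stretches. The windows were also shorter than the 78156 bp around Smox. Stretches as long as this one were rarer, 68 others among 29972 distances between summits, 5 of them on X and 8 with at least 22 genes. The most gene-rich of these others held 111 genes. Together these others held the middles of 3.59% of protein-coding genes. A raised control signal at the locus was not tested, since the control reads were not analysed here.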
